A study of Mus musculus with 21 samples.

How the data were processed

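Total RNA was extracted with Isogen and labelled with biotin by the GeneChip WT terminal labelling and Ambion WT expression kits, per the labels' protocols. ES and iPS cells were kept in ES cell medium, and MEFs in medium with 10% FBS that was replaced by ES cell medium from day 4 after infection, per the labels' protocols. The deposited value of each transcript cluster is an intensity on a linear scale, made with RMA per the submitters' processing notes. The version of RMA, the annotation used and whether all arrays were processed together are not given in the sources used here. That the scale is linear was read from the values, which reached 24948 and had medians of 66.7 to 112.5 per array. The difference in distribution between 9 and 12 arrays means that the sets look as though they were normalized separately.

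All 21 columns were matched to a sample, with 0 left over. Groups came from the sample labels, with 3 arrays in each of 7 groups. The genotype label of the vector MEFs gives a Nanog-GFP transgene only. Log2 of the value + 1 was used, and no filter was applied. Of 28874 transcript clusters 23410 were listed in the platform's annotation. Of these 21789 carried 1 gene symbol and 1621 carried several, and 5464 clusters were not listed. Genes were taken from clusters with 1 symbol, and of the 999 genes with more than 1 cluster the cluster with the highest mean over all arrays was kept, which gave 19938 genes. Chromosomes came from the annotation of assembly GRCm38.p6, to which 19856 genes were matched by gene identifier. The genome build of the array's probes is not given in the sources used here, so no coordinates are printed.

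Fits were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior). The comparison of ES cells with vector MEFs used the 12 arrays of the pluripotent groups and the vector MEFs, the comparisons among MEFs used the 12 MEF arrays, and those among pluripotent groups used their 9 arrays. Tests were 2-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. SE stands for the standard error of the log2 change in limma, and SD for the standard deviation of 3 arrays. For 32 lists of genes written down by function, camera in limma was run with a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the data, and its p-values were adjusted over the lists of a comparison. Genes called at a log2 difference of at least 2 between ES cells and vector MEFs made up the ES-high and MEF-high sets. The delivered genes were left out of all lists and sets.

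The comparisons, lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, the delivered and deleted genes and Nanog. It adds the 5 called genes with the largest rise and the 5 with the largest fall among those whose groups do not overlap, which 10% of genes show by chance with 3 arrays against 3. It also adds up to 3 called members of the naive-state list and of each of the 6 lists with the lowest camera p, and 1 called member of each list of another cell type. Members of a list that moved against it, and genes said to have been chosen later, fall outside the rule. The replicate numbers of the MEF groups were checked as possible pairs and not used as such. For overlaps of comparisons that share control arrays, unchanged groups were simulated 100 times against the same number of shared arrays.

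The procedure was tested on simulated data with the same groups. With 100 genes changed by a log2 of 1 or 2 in the design of the KOSMBAN and KOSM MEFs, 87 and 95 were recovered with 13 false calls. In the design of the KOBAN and KOSM clones 49 and 86 were recovered with 9 false calls. A 16-gene list moved by 0.5 was found by camera, at an unadjusted p under 0.05, in 20 of 20 draws in each. The simulated genes varied independently of each other. The estimated correlation among pluripotent arrays was 0.465 for the fibroblast list and 0.851 for the 2-cell-like list. The simulation thus does not test camera on lists of correlated genes. The alternatives were quantile normalization of the fitted arrays, centring of each array on its median, leaving out the dimmest 30% of genes, an intensity trend with a robust prior, array weights, a fit of the compared groups only or of all arrays, the mean of all clusters of a gene, a minimum of 2-fold, replicate numbers as a block in MEFs, and leaving out each array in turn. Clusters with several genes or none were left out of the gene table. Binding, methylation and protein were not analysed here.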

Results

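Gene expression was measured in mouse cells on 21 Affymetrix Gene ST arrays, which fell into 7 groups of 3. The pluripotent cells were the embryonic stem (ES) cell lines TT2, R1 and E14, 3 induced pluripotent stem (iPS) cell clones made with Klf4, Oct4, Sox2 and c-Myc (KOSM), and 3 KOBAN clones, for which Th2a, Th2b and p-Npm stood in for Sox2 and c-Myc. The mouse embryonic fibroblasts (MEFs) were infected with empty retroviral vector, with KOSM, or with KOSM together with Th2a, Th2b and p-Npm (KOSMBAN). A further group of MEFs lacked Th2a and Th2b and received KOSM. Fibroblasts were harvested on day 7 after infection. Th2a and Th2b are variants of histones H2A and H2B, whose genes are H2ac1 and H2bc1 on chromosome 13 (assembly GRCm38.p6). The form of Npm that the labels call p-Npm is not given in the sources used here, so the nucleophosmin genes Npm1 (chromosome 11) and Npm2 (chromosome 14) were both read. The series title gives the purpose, which was the effect of these oocyte-enriched histones and of Npm on the generation of iPS cells. Because the replicates of the pluripotent groups were different ES lines or clones, their p-values reflect the spread between lines or clones. That spread is pooled over all groups of a fit, compared or not. The SD over genes of the difference between arrays was 0.524 to 0.964 among ES lines and 0.223 to 0.383 among clones of a kind. P-values between the kinds of clone thus include the spread of ES lines, and those against ES cells borrow the smaller spread of the clones. The labels call the MEF replicates biological, but from how many embryos or lines they came is not given in the sources used here. Their p-values may reflect the spread between cultures only. Differences between MEF lines could then pass as effects of the genotype.

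The deposited values fell into a pair of sets. In the MEFs that received factors (9 arrays) the median intensity of an array was 107.6 to 112.5 and the maximum 15720 to 16775, whereas in the other 12 arrays the median was 66.7 to 72.3 and the maximum 22682 to 24948. No array was a copy of another. The number of arrays, 3 per group, limited the precision of every value.

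**Figure D1:**
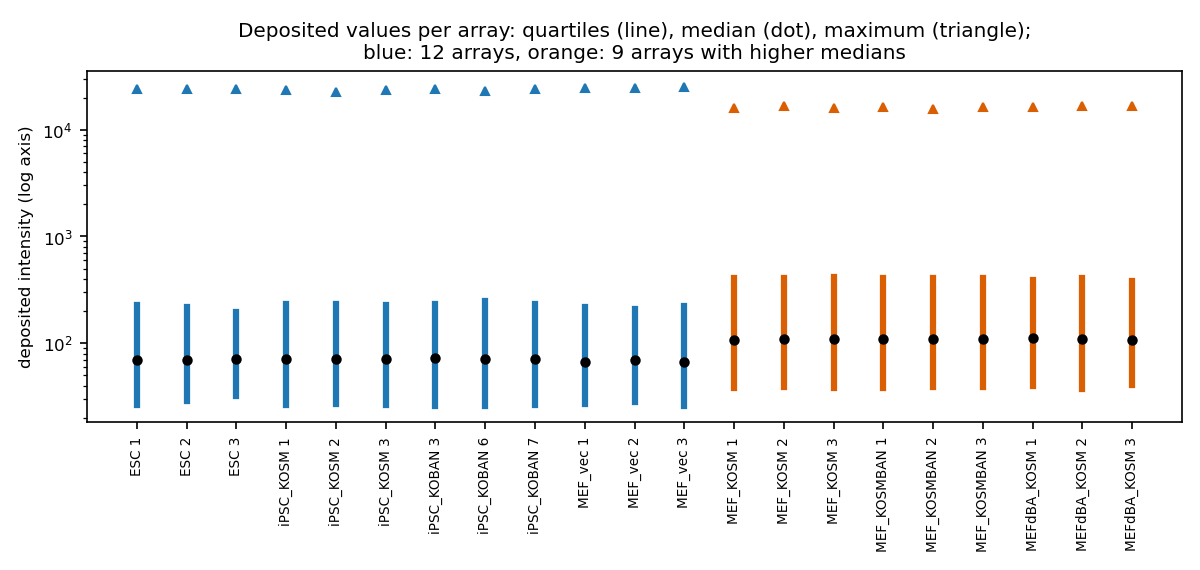
Deposited intensity per array on a log axis, with the quartiles as a line, the median as a dot and the maximum as a triangle (blue, 12 arrays; orange, the 9 arrays of MEFs with factors). The medians of the orange arrays, 107.6 to 112.5, all lay above those of the blue arrays, 66.7 to 72.3.

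The transcripts of the delivered factors were read first. Pou5f1, the gene of Oct4, had a mean intensity of 33 ± 6.04 (SD, n = 3) in vector MEFs, 1520 ± 16.6 in KOSM MEFs, 1480 ± 26.5 in KOSMBAN MEFs and 1790 ± 206 in deficient MEFs, against 3680 ± 934 in ES cells. H2ac1 stood at 2310 ± 140 in KOSMBAN MEFs against 311 ± 16.6 with KOSM alone and 5760 ± 727 in ES cells, and H2bc1 at 831 ± 82.1 against 194 ± 17.4 and 753 ± 160. Npm2 was 62.7 ± 3.65 in KOSMBAN MEFs and 30.2 ± 4.46 in KOSM MEFs, both in the lower part of the array's range. In the KOBAN clones H2ac1 was 4810 ± 497, near the 6090 ± 338 of the KOSM clones. Sox2 read 39.5 ± 2.37 in KOSM MEFs and 28.9 ± 5.51 in vector MEFs, against 1640 ± 626 in ES cells. In all MEFs with factors Sox2 lay in the dimmest 30% of genes, at percentiles of 21.6 to 24.1, so these arrays do not show its delivery, and the group names follow the labels. In the deficient MEFs H2ac1 read 304 ± 23.8 and H2bc1 194 ± 27.4, the same as in wild-type KOSM MEFs within the spread. Where the probes lie relative to the deletion was not known, so these readings check nothing about it. What the MEF level of these probes measures is therefore uncertain, and so is the size of any fold of H2ac1 or H2bc1 against it. Endogenous Nanog was 77.1 ± 3.89 in KOSM MEFs, 76.4 ± 4.95 in KOSMBAN MEFs and 3030 ± 414 in ES cells.

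**Figure D2:**
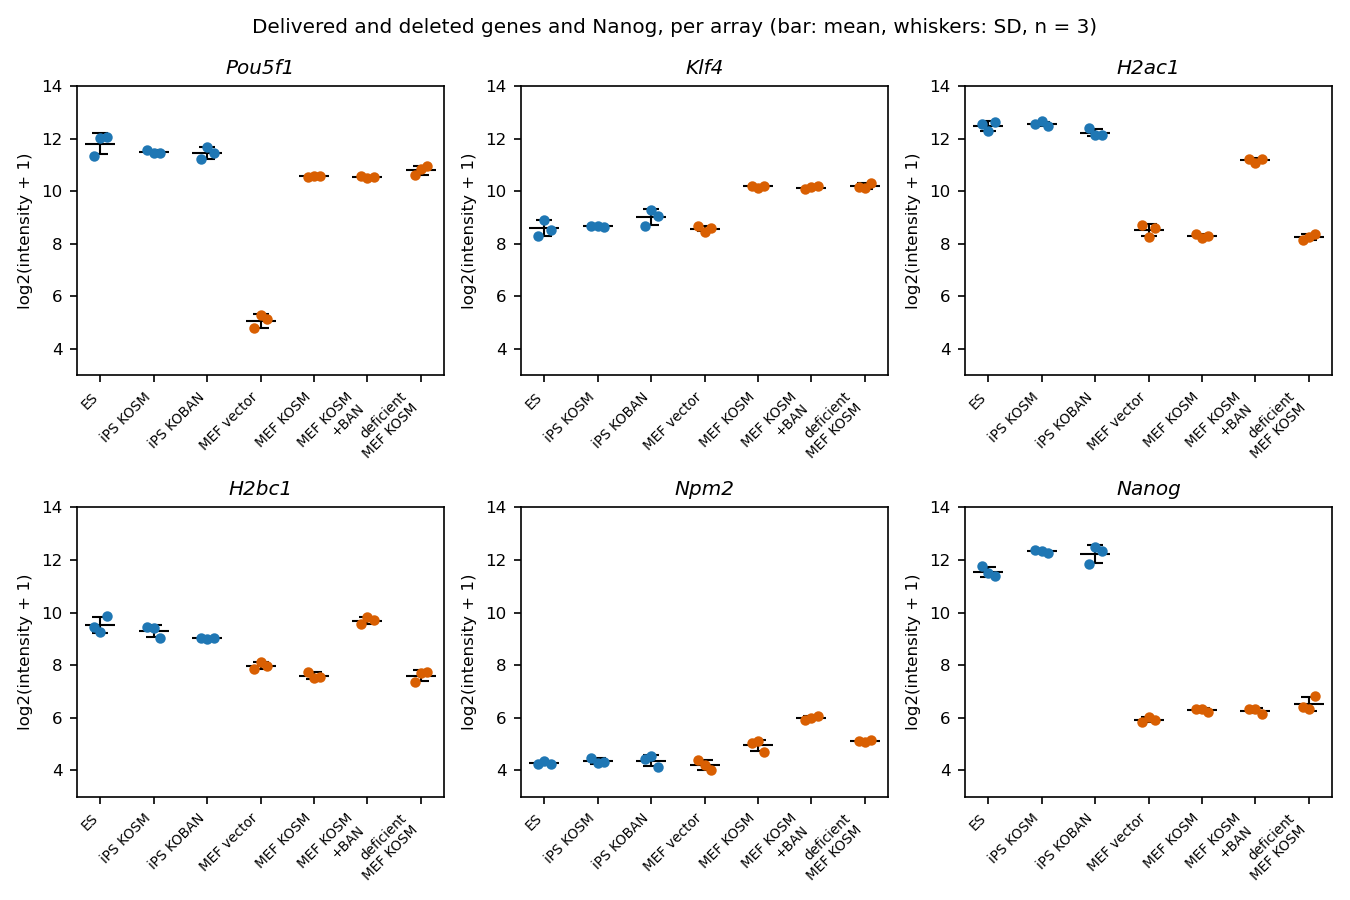
Log2 of intensity + 1 on each array for Pou5f1, Klf4, H2ac1, H2bc1, Npm2 and Nanog (blue, pluripotent groups; orange, fibroblasts), with bars at the mean and whiskers at the SD, n = 3. Among the MEFs, H2ac1 and H2bc1 were high only in the KOSMBAN arrays, with mean intensities of 2310 and 831, and Nanog stayed low in all, at 59.7 to 92.3.

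ES cells were compared with vector MEFs as a reference for the difference between the pluripotent and the fibroblast state. The vector MEFs had been infected with retrovirus, and no uninfected MEFs were measured. Effects of cell state, infection and culture cannot be told apart in this comparison, nor in the ES-high and MEF-high sets taken from it. Regulators of pluripotency were far higher in ES cells: Pou5f1 by 6.74 on the log2 scale (SE 0.21, limma adjusted p = 2.78e-09), Nanog by 5.64 (SE 0.17, adjusted p = 2.78e-09) and Sox2 by 5.71 (SE 0.26, adjusted p = 3.21e-08). Dppa5a, an RNA-binding protein of ES cells, and Tdgf1, a co-receptor of Nodal, rose by 7.02 (SE 0.2) and 6.58 (SE 0.37). The zinc finger genes Zfp980 and Zfp640 were at least 33-fold and 23.1-fold higher. Detection calls were not used here, so where the dimmer group lay in its dimmest 30% of genes a fold is given as a minimum against the 30th percentile, a choice made after the data were seen, while log2 changes are those of the fit. Both zinc finger genes belong to families of similar copies, so which copy was read is uncertain. Extracellular matrix genes were the mirror image, with Postn (periostin) lower by 131-fold (log2 -7.04, SE 0.36, adjusted p = 8.17e-08), and Dpt and Aspn lower by at least 43.4-fold and 30.1-fold. The interferon-induced gene Ifit3 was at least 90.4-fold lower (-7.39, SE 0.19, adjusted p = 1.76e-09) and the acute-phase gene Saa3 at least 92.3-fold. Both histone variants were higher in ES cells, H2ac1 by 15.6-fold (3.96, SE 0.15) and H2bc1 by 2.93-fold (1.55, SE 0.17), and so was Npm1 (1.96-fold, adjusted p = 0.00639), but not Npm2 (0.07, SE 0.14, adjusted p = 0.766) or Klf4 (0.01, SE 0.18, adjusted p = 0.97). The folds of both histones rest on a MEF level of uncertain source. Myc was not called (-1.81, SE 0.68, adjusted p = 0.0617), although it was without E14 (-2.61, adjusted p = 0.00176).

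Of 19938 genes, 3248 were higher and 3262 lower in ES cells. All 20 measured members of the list of other pluripotency genes were higher (20 adjusted over the list alone, camera adjusted p = 1.35e-18), as were 15 of the 16 naive-state genes (15 adjusted over the list alone, adjusted p = 4.75e-09), led by Nr0b1 (5.87) and Fbxo15 (5.48). The exception was Stat3, the signal transducer of the cytokine LIF, which was lower (-0.81, SE 0.15, adjusted p = 0.00123). All 28 fibroblast and mesenchymal genes and all 15 interferon response genes were lower, over all genes and adjusted over the list alone (adjusted p = 5.22e-20 and 1.35e-18). Cell cycle genes were higher in 16 of 19 (18 adjusted over the list alone, adjusted p = 1.94e-11), germ line and meiosis genes in 15 of 19 (17, adjusted p = 3.92e-08), and epithelial genes in 17 of 22 (18, adjusted p = 1.21e-07). Mael, which guards the germ line against transposons, rose by 4.87 (SE 0.2) and E-cadherin, Cdh1, by 4.55 (SE 0.3). With an estimated correlation, 4 of the 15 passing lists still passed: other pluripotency genes (adjusted p = 0.00999), cell cycle (0.0135), interferon response (0.044) and naive state (0.0476). The fibroblast list (adjusted p = 0.0766 with an estimated correlation), germ line (0.0591) and epithelial (0.0591) lists did not.

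Among the remaining passing lists, glycolysis had 9 of 12 genes higher (10 adjusted over the list alone, camera adjusted p = 6.78e-06), chromatin modifiers 8 of 19 (10, adjusted p = 0.000213), ribosome biogenesis 9 of 16 (10, adjusted p = 0.000269) and oxidative phosphorylation 5 of 14 (6, adjusted p = 0.0279; 0.0916 without TT2 and 0.068 without vector replicate 2). The count of chromatin modifiers depended on E14, since without it 15 were higher (16 higher and 1 lower adjusted over the list alone) and their mean was 1.484, against 1.132 with it (adjusted p = 0.0504 with an estimated correlation). In the list of linker and variant histones 7 of 12 were higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.00833), and the lower pair was H1f2 (-1.54, SE 0.25), a linker histone, and Macroh2a2 (-0.55, SE 0.17). Primed-state genes had 5 of 11 higher and 1 lower (6 and 1, adjusted p = 0.00697). Immediate early genes had 6 of 9 lower (6 adjusted over the list alone, adjusted p = 0.004), with Ier2 alone higher (0.86, SE 0.24). Imprinted genes had 10 of 18 lower (11 adjusted over the list alone, adjusted p = 0.00538), among them Igf2 (-4.48, SE 0.39), a growth factor. Phlda2 (4.45, SE 0.26) and Peg10 (2.56, SE 0.37), both imprinted placental genes, went the other way. With an estimated correlation none of these 8 lists passed, with adjusted p = 0.189 for glycolysis, 0.232 for chromatin modifiers, 0.0867 for ribosome biogenesis and for oxidative phosphorylation, 0.0766 for the histones and for imprinted genes, 0.272 for the primed state and 0.35 for immediate early genes.

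KOSM MEFs were compared with vector MEFs for the early response to the factors. Besides Pou5f1 (5.50, SE 0.12, limma adjusted p = 1.19e-10) and Klf4 (1.60, SE 0.08, adjusted p = 1.93e-08), strong rises were those of Sostdc1, a secreted antagonist of BMP and Wnt signals (6.22, SE 0.11, at least 52.3-fold), E330013P04Rik (5.28) and Fmo1, a flavin monooxygenase (5.23, SE 0.08, 37.5-fold). The acute-phase genes Saa3 (-3.71, SE 0.2, 13.1-fold) and Lcn2 (-2.57, SE 0.13, 5.95-fold) and the mechanical stress gene Ankrd1 (-2.61, SE 0.1, 6.1-fold) fell. Epithelial keratins and cadherin rose, with Krt19 at 2.09 (SE 0.12), Krt8 at 1.49 and Cdh1 at 1.11 (SE 0.09), but so did mesenchymal genes, with Twist1 at 2.47 (SE 0.1) and Tgfbi at 2.26 (SE 0.1). Fabp4, a fatty acid binding protein of adipocytes, rose by 2.28 and Tek, an endothelial receptor, by 3.71. Each of these kept its direction and its call after quantile normalization (Pou5f1 4.96, Klf4 0.75, Sostdc1 5.72, Fmo1 4.65, Saa3 -4.22, Lcn2 -3.30, Ankrd1 -3.38, Krt19 1.19, Cdh1 0.58, Twist1 1.61, Tgfbi 1.51, Fabp4 1.65, Tek 3.08) and after each array was centred on its median. H2bc1 was lower (-0.38, and -1.30 after quantile normalization). H2ac1 was not called as deposited (-0.24, adjusted p = 0.0692) but was after quantile normalization (-1.15, adjusted p = 8.26e-06) and after centring (-0.92, adjusted p = 0.000119). Myc (0.28) and Nanog (0.36) were called higher as deposited but were -0.54 and -0.21 after quantile normalization, and Sox2 (0.46) was 0.02 after it and -0.22 after centring. Without 1 array of vector MEFs, replicate 1, Nanog (adjusted p = 0.052) and Myc (adjusted p = 0.0919) were not called, nor was Myc without KOSM replicate 1 (0.0543) or 3 (0.0515).

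These groups lay in different sets of values, so the value set and the treatment cannot be told apart. As deposited, 15490 genes were higher and 515 lower, and the median log2 change of all genes was 0.617. Quantile normalization moved that median to -0.026 and gave 9783 genes, 6933 of them among those called as deposited; centring moved it to -0.06 and gave 10834, of which 7451 were shared. At least 2-fold, 4755 genes were called as deposited and 1009 after quantile normalization. Counts within lists follow the same shift, whereas camera sets a list against the other genes. By camera 8 of 32 lists passed, and none with an estimated correlation. Adipocyte genes were above the other genes (8 of 8 higher over all genes and adjusted over the list alone, adjusted p = 0.0403; adjusted p = 0.459 with an estimated correlation). Germ line and meiosis genes were below them (5 of 19 higher and 7 lower by either adjustment, adjusted p = 1.04e-08; adjusted p = 0.0566 with an estimated correlation). The mean level of this list was 4.68 in vector and 4.64 in KOSM MEFs, under the 30th percentiles of 5.38 and 5.85, and 13 of its 19 genes were dim in both groups. Genes dim in both moved by a median of 0.392 and the others by 0.744, so part of this rank follows from the level. The list mean of -0.04 was still under the 0.212 to 0.614 (central 95%) of 1000 random sets of genes of like level, a comparison added after the data were seen, and the cause was not tested. The fibroblast list was also below the other genes (17 of 28 higher and 4 lower, adjusted p = 0.00894; adjusted p = 0.477 with an estimated correlation). So were the glycolysis (adjusted p = 0.00534), other pluripotency (0.00846), naive state (0.0148), macrophage (0.0241; 0.0693 without vector replicate 2) and epithelial (0.0244) lists, each at adjusted p = 0.558 with an estimated correlation. Their mean log2 changes were above 0, at 0.294 for the naive state, so the test and the mean differed in sign. Against sets of like level the fibroblast (0.491, sets 0.347 to 0.723), macrophage (0.306, sets 0.278 to 0.741) and other pluripotency lists (0.38, sets 0.371 to 0.8) lay inside the range, the glycolysis, naive state and epithelial lists under it and the adipocyte list over it. Of the sets defined by the ES and MEF comparison, which were chosen on these samples and are not independent evidence, the 784 MEF-high genes were below the other genes (mean 0.613, adjusted p = 9.46e-06; adjusted p = 0.224 with an estimated correlation) and the 381 ES-high genes did not pass (mean 0.779, adjusted p = 0.759). The mean of the MEF-high set was below 0 after quantile normalization and after centring, so it too followed the scaling.

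KOSMBAN MEFs were compared with KOSM MEFs for the early effect of adding Th2a, Th2b and p-Npm. The 3 genes called were H2ac1, higher by 7.39-fold (2.89, SE 0.11, limma adjusted p = 3.33e-07), H2bc1 by 4.26-fold (2.09, SE 0.12, adjusted p = 1.3e-05) and Npm2, dim in KOSM MEFs, by 1.04 on the log2 scale (SE 0.12, adjusted p = 0.0102). Here too the size of both histone folds is uncertain. Npm1 was not called (-0.33, SE 0.37, adjusted p = 1), nor was Pou5f1 (-0.04, SE 0.12), Klf4 (-0.04, SE 0.08), Sox2 (0.06, SE 0.13), Myc (-0.15, SE 0.1) or Nanog (-0.01, SE 0.12), all with adjusted p = 1. With limma 3 genes were higher and 0 lower, and 287 genes had an unadjusted p under 0.05. With array weights, from 0.0786 to 4.38 in this fit, 468 genes were higher and 329 lower. Npm2 was not called without KOSMBAN replicate 2 (adjusted p = 0.0818) or replicate 3 (adjusted p = 0.107), nor when only the 6 arrays of both groups were fitted (adjusted p = 0.171). Without replicate 3 of the deficient MEFs, which shares the fit, 5 genes were called, the added ones being Lrrn4 (-0.88, SE 0.07, adjusted p = 0.000369) and Upk3b (-0.77, SE 0.1, adjusted p = 0.0283), both genes of mesothelium. This fit was chosen after the data were seen.

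None of the 16 naive-state genes was called in KOSMBAN MEFs, over all genes or adjusted over the list alone (mean 0.064, camera adjusted p = 0.4), and the 738 X-linked genes did not pass (mean -0.009, adjusted p = 0.906). Interferon response genes were slightly higher as a list (mean 0.297, adjusted p = 6.94e-11), with 0 of 15 called over all genes and 1 adjusted over the list alone. Without KOSM replicate 3 the mean was 0.167 (adjusted p = 6.52e-05), and without replicate 1 it was 0.394. All 15 leaned upward, the antiviral GTPase Mx1 by 0.52 (SE 0.32) and the membrane tether Bst2 by 0.45 (SE 0.14). Cell cycle genes (19 measured, mean -0.151, adjusted p = 2.73e-06), ribosome biogenesis genes (16 measured, mean -0.123, adjusted p = 0.00366) and immediate early genes (9 measured, mean -0.082, adjusted p = 0.0166) were slightly lower, with none called by either adjustment. Ribosome biogenesis genes did not pass without KOSM replicate 1 or KOSMBAN replicate 2 (adjusted p = 0.0945 and 0.294), nor did immediate early genes without these or KOSM replicate 3 (adjusted p = 0.0508). None of the 4 passed with an estimated correlation (adjusted p = 0.287 for interferon, cell cycle and ribosome biogenesis, 0.975 for immediate early genes). The ES-high genes had a mean of -0.013 (adjusted p = 0.0497) and the MEF-high genes one of 0.034 (adjusted p = 0.028), both at adjusted p = 0.541 with an estimated correlation.

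Deficient MEFs were compared with wild-type MEFs, both with KOSM, for the part that endogenous Th2a and Th2b play. Imprinted genes fell: Dlk1, a Notch-like membrane protein of growing tissue, by 2.97-fold (-1.57, SE 0.12, limma adjusted p = 3.28e-05), Cdkn1c, a cell cycle inhibitor, by 2.14-fold (-1.10, SE 0.13, adjusted p = 0.000506) and the growth factor Igf2 by 1.87-fold (-0.91, SE 0.06, adjusted p = 2.55e-05). The noncoding RNA Meg3, from the same imprinted domain as Dlk1 but from the maternal copy, fell too (-0.71, SE 0.09, adjusted p = 0.00105). Other strong falls were those of Trim30d (-4.45, SE 0.15, at least 9.32-fold, adjusted p = 3.35e-08) and Trim12a (-3.84, SE 0.38, at least 9.29-fold), of tripartite motif families with similar copies that probes may not separate, of the phosphatase gene Ptprv (-3.02, SE 0.12), and of Sfrp4, a secreted Wnt antagonist (-2.76, SE 0.09, 6.78-fold). Angptl7 (2.38, SE 0.21, 5.2-fold), Slfn2 (2.27, SE 0.2), the cartilage matrix gene Comp (2.00, SE 0.12, 3.99-fold), Cxcl15 (1.89, SE 0.19) and Pianp (1.88, SE 0.15) rose. The junction gene Dsp (0.88, SE 0.12), Krt8 (0.78, SE 0.12) and Cdh1 (0.70, SE 0.09) rose, whereas Krt19, another epithelial keratin, fell (-0.59, SE 0.12, adjusted p = 0.0227). Nanog (0.24, SE 0.12, adjusted p = 0.313), Pou5f1 (0.23, adjusted p = 0.334) and Npm1 (-0.89, SE 0.37, adjusted p = 0.258) did not pass.

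In all, 263 genes were higher and 323 lower in deficient MEFs. The imprinted list had 4 of 18 genes lower and none higher (12 and 1 adjusted over the list alone, mean -0.524, camera adjusted p = 1.22e-10), and it passed with an estimated correlation too (adjusted p = 0.00219). H19 was not measured. Epithelial genes were higher as a list (3 of 22 higher and 1 lower by either adjustment, adjusted p = 0.0142), as were cartilage and bone genes (2 of 10, 3 adjusted over the list alone, adjusted p = 0.0142) and trophectoderm genes (1 of 11, 3 adjusted over the list alone, adjusted p = 0.0232), the last with the growth factor receptor Fgfr2 (0.71, SE 0.07, adjusted p = 0.000189). Lower as lists were cell cycle genes (19 measured, none called, mean -0.188, adjusted p = 0.0142), chromatin modifiers (19 measured, none called, mean -0.224, adjusted p = 0.0439) and fibroblast genes (1 of 28 lower, 2 adjusted over the list alone, mean -0.157, adjusted p = 0.0439). None of these 6 passed with an estimated correlation (adjusted p = 0.593 for epithelial genes, 0.498 for chromatin modifiers and 0.53 for the others). None of the 16 naive-state genes was called (mean 0.155, adjusted p = 0.169), and X-linked genes did not pass (mean -0.065, adjusted p = 0.173). Of the MEF-high genes 20 were higher and 85 lower (41 and 126 adjusted over the list alone, mean -0.215, adjusted p = 3.89e-11; adjusted p = 0.0613 with an estimated correlation), and ES-high genes did not pass (mean 0.065, adjusted p = 0.208).

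Replicate 3 of the deficient MEFs stood apart from its group, with a median correlation of 0.969 to its other arrays, against 0.983 and 0.984 for replicates 1 and 2. Without it the count of called genes was 795, and without KOSM replicate 1, 2 or 3 it was 311, 294 or 307. Dlk1 (-1.72), Cdkn1c (-1.22) and Igf2 (-0.92) kept their calls without deficient replicate 3, and the imprinted list passed by both tests (adjusted p = 2.59e-10; adjusted p = 0.00479 with an estimated correlation). Without it the fibroblast list (mean -0.066, adjusted p = 0.1) and the chromatin modifiers (mean -0.063, adjusted p = 0.189) did not pass. Without deficient replicate 1 the imprinted list was the only one of the 7 to pass, and the epithelial, cartilage and bone, trophectoderm, chromatin modifier and fibroblast lists had an adjusted p = 0.0584 and the cell cycle genes 0.128. In a fit of the 6 arrays of these groups 214 genes were called and Krt8 was not (adjusted p = 0.0514). In a fit of all 21 arrays 226 were called, without Igf2, Dsp, Krt8, Cdh1 and Fgfr2. At least 2-fold, 35 genes were higher and 68 lower.

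**Figure D3:**
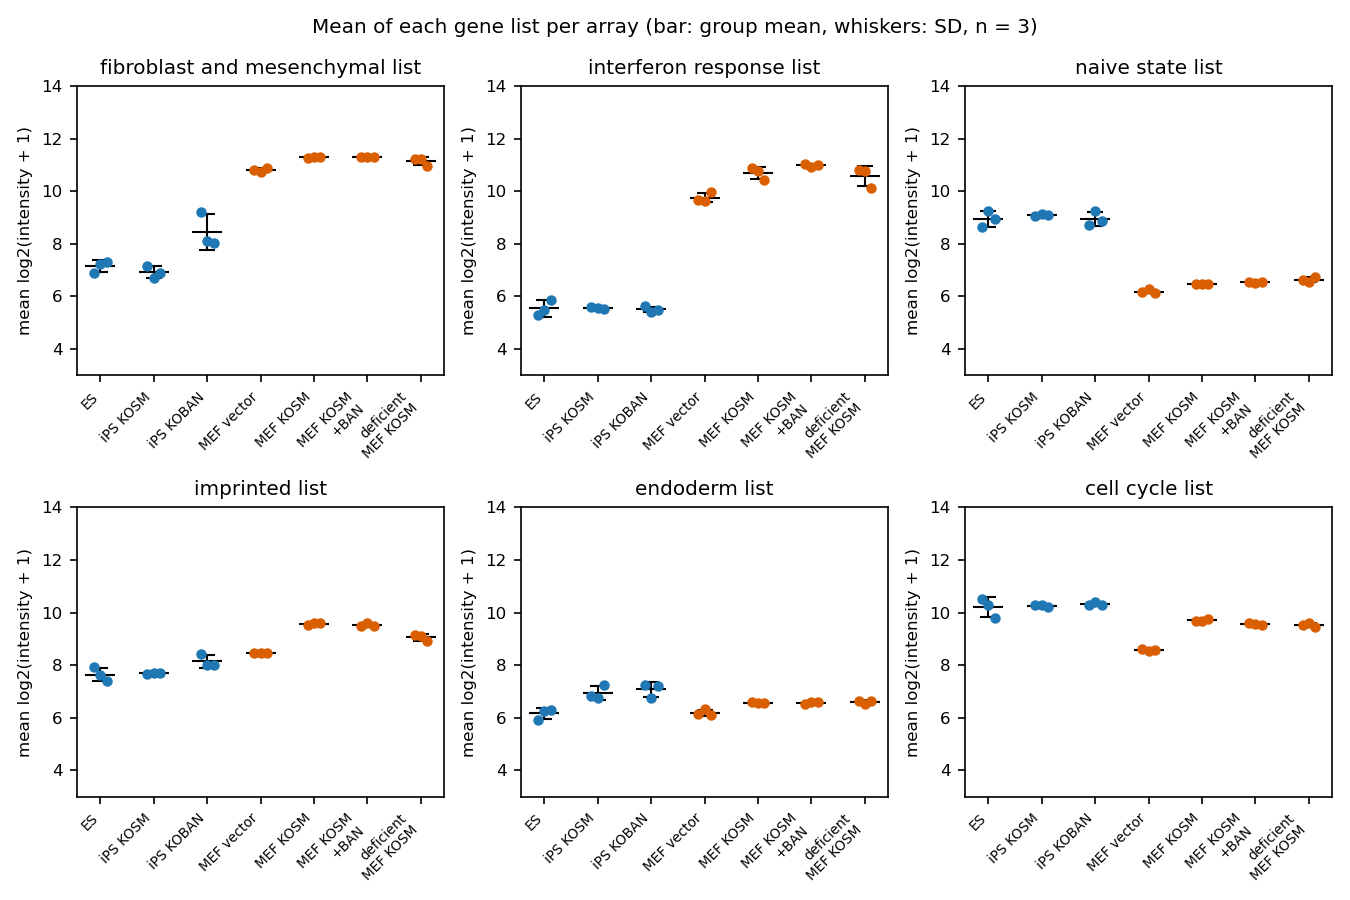
Mean log2 intensity of the members of 6 gene lists on each array, with bars at the group mean and whiskers at the SD, n = 3 (blue, pluripotent groups; orange, fibroblasts). Imprinted genes were lower in deficient than in wild-type KOSM MEFs (9.06 against 9.58), and fibroblast genes were higher in KOBAN than in KOSM clones (8.45 against 6.91).

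The effects of adding and of lacking the histones were set side by side. No gene was called in both comparisons, where 0.0396 (higher in both) and 0.0486 (higher on addition, lower in deficient cells) would overlap if the calls were independent. The log2 changes correlated across genes with r = 0.393, where unchanged groups that share the same KOSM arrays gave 0.5 in simulation. The covariance was 0.0117 against a simulated 0.0126. That simulated r is the one of groups with equal spread. The SD over genes of the difference between arrays was 0.12 to 0.159 among KOSM MEFs, 0.131 to 0.231 among KOSMBAN MEFs and 0.147 to 0.53 among deficient MEFs. The simulation thus cannot tell how much of the correlation comes from the shared arrays. Genes are not independent replicates. At an unadjusted p under 0.01, 14 genes were higher on addition and lower in deficient cells, where 1.31 would be by independent calls, and 16 were lower in both (0.641 by independent calls). Leaving out 1 MEF array at a time gave 3 to 19 genes higher on addition and lower in deficient cells and 8 to 40 lower in both. These ranges were read after the data were seen.

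KOSM clones were compared with ES cells to ask how close the iPS state came to that of ES lines. Of 14 endoderm genes 3 were called, all higher: the transcription factor Gata6 at 6.26-fold (2.65, SE 0.34, limma adjusted p = 0.024), the endocytic receptor Cubn at 9.71-fold (3.28, SE 0.53, adjusted p = 0.0406) and the adaptor Dab2 at 5.43-fold (2.44, SE 0.37, adjusted p = 0.0347), although another transcript cluster of Dab2 moved by 0.04 only and their mean was not called (1.24, adjusted p = 0.0507). The largest rises were those of Elobl (4.09, SE 0.38, 17-fold) and 2210409E12Rik (3.31, SE 0.3), followed by the proteoglycan Srgn (3.15, SE 0.37, 8.9-fold). Lefty2, a feedback inhibitor of Nodal, fell by at least 4.02-fold (-2.03, SE 0.26, adjusted p = 0.024), and the fatty acid transporter Slc27a2 by 5.19-fold (-2.38, SE 0.37, adjusted p = 0.036). The stress response genes Chac1 (1.30, SE 0.2) and Atf4 (1.05, SE 0.17) and the germ line gene Mael (1.73, SE 0.2) rose. Pou5f1 (-0.31, SE 0.21, adjusted p = 0.45), Sox2 (0.37, adjusted p = 0.488), Nanog (0.78, SE 0.18, adjusted p = 0.114), H2ac1 (0.09) and H2bc1 (-0.24) were not called. Nanog was called in the fit of all 21 arrays (adjusted p = 0.00357) and without TT2 (0.88, adjusted p = 0.0218), as was Pou5f1 without TT2 (-0.55, adjusted p = 0.0492). The mean intensity of Myc was 88.7 ± 8.93 (SD) in KOSM clones and 303 ± 278 in ES cells, with 47.5 to 599 among the ES lines.

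In total 87 genes were higher and 20 lower in KOSM clones. The count rested on single arrays: it was 2970 without TT2, 48 without R1 and 233 without E14, and 3, 2 and 0 without clones 1, 2 and 3, when none of the genes named here was called. Cubn was not called after quantile normalization (adjusted p = 0.0551), nor Atf4 with an intensity trend and robust prior (adjusted p = 0.0717). In a fit of the 6 arrays of these groups it was 6, and in a fit of all 21 arrays 2653. Of 32 lists 7 passed, and none with an estimated correlation (adjusted p = 0.603 to 0.761). Higher were endoderm (3 of 14 higher, 4 adjusted over the list alone, camera adjusted p = 0.00437) and 2-cell-like genes (0 of 4, 3 adjusted over the list alone, mean 1.186, adjusted p = 0.00437). So were heat shock and stress genes (2 of 9 higher, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00573), p53 targets (0 of 13, mean 0.474, adjusted p = 0.029) and germ line genes (1 of 19, 3 adjusted over the list alone, adjusted p = 0.0376). Lower were primed-state genes (0 of 11, 2 adjusted over the list alone, mean -0.421, adjusted p = 0.00951) and other pluripotency genes (1 of 20 lower, 3 adjusted over the list alone, mean -0.468, adjusted p = 0.0376). Without TT2 none of the 7 passed (adjusted p = 0.0857 to 0.122). The germ line list did not pass without E14 (adjusted p = 0.0932) or clone 1 or 2 (adjusted p = 0.0646 and 0.175) either, nor did other pluripotency genes without R1 (adjusted p = 0.291) or clone 1 (adjusted p = 0.0646). Naive-state genes did not pass (mean 0.163, adjusted p = 0.226), except without R1 (mean 0.308, adjusted p = 0.0299). Of the MEF-high genes, a set chosen as low in these ES arrays, 21 were higher and none lower (mean 0.158, adjusted p = 5.47e-05; adjusted p = 0.75 with an estimated correlation).

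KOBAN clones were also compared with ES cells. Fabp7, a fatty acid binding protein of neural progenitors, was at least 23.5-fold higher (5.10, SE 0.3, limma adjusted p = 0.000918) and Srgn 17.2-fold (4.11, SE 0.37, adjusted p = 0.00332). Of 28 fibroblast and mesenchymal genes 3 were called, all higher: Postn 14.2-fold (3.83, SE 0.41, adjusted p = 0.00903), the collagen crosslinker Lox 8.25-fold (3.04, SE 0.44, adjusted p = 0.0199) and the cadherin Cdh11 5.66-fold (adjusted p = 0.019). The endoderm genes Dab2 (3.30, SE 0.37, with the other cluster at 0.05), Cubn (3.95, SE 0.53) and Gata6 (2.23, SE 0.34) were higher again. Among imprinted genes Plagl1, a zinc finger growth regulator, rose by 4.73-fold (2.24, SE 0.27) and Phlda2 fell by 4.66-fold (-2.22, SE 0.27), both with adjusted p = 0.0117. The DNA methyltransferase gene Dnmt3b fell (-0.91, SE 0.16, adjusted p = 0.0363), and so did the DNA repair gene Mutyh (-1.86, SE 0.16, 3.62-fold). The Y-linked genes Eif2s3y (1.57, SE 0.27) and Kdm5d (1.28, SE 0.2) were higher, and Kdm5d was also called higher in KOSM clones (1.31). Nanog (0.67, adjusted p = 0.12) and H2bc1 (-0.52, adjusted p = 0.168) were not called, although both were in the fit of all 21 arrays (adjusted p = 0.00785 and 0.0254) and Nanog without TT2 (adjusted p = 0.0257).

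Here 159 genes were higher and 47 lower. The count was 4475 without TT2, 127 without R1 and 369 without E14, and 64, 70 and 41 without clones 3, 6 and 7. Fabp7, Srgn, Postn, Dab2, Plagl1 and Mutyh were called in each of these 6 fits. Lox and Gata6 were not called without clone 3, 6 or 7 (adjusted p = 0.0596 to 0.0843 and 0.0627 to 0.109), nor Cdh11 without clone 6 (adjusted p = 0.0627), nor Cubn without clone 3 or 7 (adjusted p = 0.0657 and 0.0696), and Dnmt3b was not called with an intensity trend and robust prior (adjusted p = 0.0733). Fitted on these 6 arrays alone the count was 21, and 4061 on all 21. Of 32 lists 9 passed, none of them with an estimated correlation (adjusted p = 0.308 to 0.784). Fibroblast genes had 3 of 28 higher and 18 adjusted over the list alone (mean 1.301, camera adjusted p = 2.86e-13; adjusted p = 0.352 with an estimated correlation). Clone 3 added to this, since without it the mean was 0.916 and 11 were higher adjusted over the list alone. Also higher were the sex-specific list (2 of 4, 4 adjusted over the list alone, adjusted p = 0.000213), endoderm (3 of 14, 4, adjusted p = 0.00103) and X-linked genes (12 of 738, 22 higher and 1 lower, adjusted p = 0.00363). So were imprinted genes (1 higher and 1 lower of 18, 3 and 1, adjusted p = 0.0103), macrophage genes (1 of 15, 1, adjusted p = 0.0123) and heat shock genes (0 of 9, 3 higher and 1 lower, adjusted p = 0.0212). The sex-specific list holds the X-inactivation transcript Xist together with Y-linked genes, so its rise does not read as a difference in sex. Primed-state genes (1 of 11 lower, 7 adjusted over the list alone, adjusted p = 0.0128) and other pluripotency genes (0 of 20, 7 lower adjusted over the list alone, adjusted p = 0.0319) were lower. Without TT2 the endoderm (adjusted p = 0.0734), macrophage (mean 0.175, adjusted p = 0.43), heat shock (adjusted p = 0.0627), primed-state (adjusted p = 0.112) and other pluripotency genes (adjusted p = 0.0826; 0.161 without R1) did not pass. Naive-state genes did not pass (mean 0.002, adjusted p = 0.489). Of the MEF-high genes, chosen as low in the same ES arrays, 98 were higher and none lower (mean 0.755, adjusted p = 7.32e-44; adjusted p = 0.0375 with an estimated correlation).

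KOBAN and KOSM clones were compared for what the choice of factors left in established clones. Fabp7 (5.35, SE 0.3, at least 25.1-fold, limma adjusted p = 6e-04), Postn (4.25, SE 0.41, at least 15.5-fold, adjusted p = 0.0056), Lox (4.01, SE 0.44, 16.1-fold, adjusted p = 0.0101), Igfbp7, a secreted binding protein (3.77, SE 0.32, 13.6-fold, adjusted p = 0.00372), and the lysozyme gene Lyz2 (3.61, SE 0.46, at least 8.07-fold, adjusted p = 0.0199) were higher in KOBAN clones, as was Plagl1 (2.25, SE 0.27, adjusted p = 0.0156). The chemokine gene Ppbp was at least 6.24-fold lower (-2.88, SE 0.28, adjusted p = 0.0056), and Pramel20 (-2.18, SE 0.31), of a family with many copies, and Gm11545 (-2.03, SE 0.18) were lower too. The oocyte homeobox gene Obox6 was lower on its brighter transcript cluster (-1.53, SE 0.24, adjusted p = 0.0469), but it was not called with the mean of both clusters (-0.91, adjusted p = 0.126) or after quantile normalization (adjusted p = 0.0655), nor was Pramel20 after it (adjusted p = 0.0526). The collagen-binding Dcn (3.31, SE 0.67, adjusted p = 0.127) and Lum (3.11, SE 0.77, adjusted p = 0.216) leaned the same way as Postn without passing. Pou5f1 (-0.03, SE 0.21), Sox2 (-0.03, SE 0.27) and Nanog (-0.11, SE 0.18) were not called, nor was H2ac1 (-0.34, SE 0.14, adjusted p = 0.559), although KOBAN clones were made with a vector for its product.

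Between the clones 38 genes were higher and 12 lower in KOBAN. The count was 25, 8 and 16 without KOSM clones 1, 2 and 3, 22, 14 and 44 without KOBAN clones 3, 6 and 7, and 152 without E14, which shares the fit. Fabp7, Igfbp7, Ppbp and Gm11545 were called in each fit without 1 clone, and Postn in all but that without KOSM clone 2. Lox was not called without KOSM clone 2 or 3 or KOBAN clone 3 or 6 (adjusted p = 0.0546 to 0.0712), nor Lyz2 in any of the 6 fits but that without KOBAN clone 7 (adjusted p = 0.0954 to 0.131), nor Plagl1 without KOSM clone 1, 2 or 3 or KOBAN clone 6 (adjusted p = 0.0611 to 0.11). With the 6 arrays of these groups, so without the spread of the ES lines, 850 genes were called, and with all 21 arrays 629. The fibroblast list was higher by 1.538 on average, with 2 of 28 genes called and 19 adjusted over the list alone (camera adjusted p = 3.07e-27; adjusted p = 0.281 with an estimated correlation). Macrophage (1 of 15, 4 adjusted over the list alone, adjusted p = 1.73e-06), sex-specific (0 of 4, 2, adjusted p = 0.00135), imprinted (1 of 18 higher, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00182) and X-linked genes (2 of 738, 6 higher and 1 lower, adjusted p = 0.047) were higher as lists. The X-linked list passed in only 1 of the 6 fits without 1 clone (adjusted p = 0.0517 to 0.105 in the other 5), and not without E14 (adjusted p = 0.0799), with means from 0.064 to 0.093. Epithelial (0 of 22, 2 adjusted over the list alone, mean -0.441, adjusted p = 5.25e-05) and 2-cell-like genes (0 of 4, 4 adjusted over the list alone, mean -1.145, adjusted p = 0.000174) were lower. In each of the 6 fits without 1 clone the epithelial list passed, but 0 of its genes were called adjusted over the list alone. With an estimated correlation none of the 7 passed (adjusted p = 0.281 to 0.487). Naive-state genes did not pass (mean -0.161, adjusted p = 0.871). Of the MEF-high genes 28 were higher and 1 lower (mean 0.597, adjusted p = 1.81e-50; adjusted p = 0.0278 with an estimated correlation).

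The changes of both kinds of clone against ES cells overlapped. They shared 43 genes that were higher and 14 that were lower, where 0.694 and 0.0471 would be shared by independent calls, and none went in opposite directions. Without KOSM clone 1, 2 or 3 the shared genes were 2, 1 and 0, all higher, and without KOBAN clone 3, 6 or 7 they were 17, 15 and 4 higher and 2, 1 and 1 lower. Leaving out TT2, R1 or E14 gave 1319, 22 and 71 higher and 1052, 8 and 31 lower, with 3 in opposite directions without TT2, all fits read after the data were seen. Among those higher in both were Gata6, Dab2, Cubn, Srgn, Wwtr1 (0.93 and 0.85 in KOSM and KOBAN clones) and the chromatin remodeller Smarca2 (1.94 and 1.67), the last 2 of them chosen after their values were seen. Shared ES arrays raise such an overlap by themselves. The covariance of the changes was 0.178 and r was 0.76, where simulated unchanged groups that share them gave 0.0403 and 0.498. That simulated r is the one of groups with equal spread. The SD over genes of the difference between arrays was 0.524 to 0.964 among ES lines and 0.223 to 0.383 among clones of a kind. The simulation thus cannot tell how much of the overlap comes from the shared ES arrays.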

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

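The tests of the poor array and of chromosome segments in this part were chosen after the result was seen. Outside the gene table, probe clusters that no comparison used also moved between deficient and wild-type MEFs with KOSM. Of the 5464 clusters that the annotation does not list, 21 were higher and 55 lower in deficient cells (limma, adjusted over all 28874 clusters), with log2 changes from -5.56 to 1.51. Of the 1621 clusters shared by several genes, 18 were higher and 15 lower, from -1.93 to 0.8. In KOSMBAN against KOSM MEFs limma called 0 in either class, and 184 and 106 had an unadjusted p under 0.05. What the unlisted clusters measure is not known, so no transcript is named for them.

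The 586 genes that differed between deficient and wild-type MEFs with KOSM raise the question of a technical source. A poor array, replicate 3 of the deficient cells, was argued against for 537 of them, which were called in the same direction without it, and stays open for the other 49, whose change without it was at the median 0.812 of that with it (0.717 to 0.965; median SE 0.104 with and 0.101 without it). Segments of another mouse strain that came along with the deletion stay open: 21 pairs of neighbouring genes of unlike name were both called, against a median of 15 in random sets (8 to 22 in the central 95%), and 27 in the comparison of KOSM with vector MEFs. On chromosome 13, which holds H2ac1 and H2bc1, 23 of 732 genes were called (3.14%), against 2.94% of all genes. The highest share was 6.16%, on chromosome 18. The share over a whole chromosome does not isolate the deleted locus. A reversal by added Th2a, Th2b and p-Npm was not seen over the called genes as a whole, where the change in deficient cells correlated with that on addition by r = 0.102, inside the 0.0262 to 0.245 of 1000 simulated draws with shared KOSM arrays, but a reversal of some genes stays open, since at an unadjusted p under 0.01 14 were higher on addition and lower in deficient cells (1.31 by independent calls; 3 to 19 without 1 array at a time), a direction that shared arrays do not favour. Those 14 included the chemokine genes Ccl5, Ccl8, Cxcl9 and Cxcl11 and the acute-phase gene Saa3, beside genes such as Dpt, Elmo1 and Gfra1. Genes that are regulated together do not count as separate reversals. The loss of the histones themselves, which the design names, remains open and was not tested apart from the background of the deficient mice.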

How the results depend on the processing

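Added after the data were seen were the fits without replicate 3 of the deficient MEFs where it was not compared, without E14 in KOBAN against KOSM clones, of the 9 arrays with the higher median, quantile normalization with a minimum of 2-fold, the lists and both overlaps without each array in turn, folds against the 30th percentile for dim levels, and lists against genes of like level in KOSM MEFs. Counts of called genes stayed within 1.5 times in 73 alternatives and moved further in 42. Of the values of named genes 2674 kept direction and side of the threshold, 202 lost the call, 31 gained one and 47 reversed, and of those of lists 148, 22, 1 and 9 did. Except where a fit with fewer arrays, genes or a minimum fold explains it, the cause was not tested. Replicate numbers in MEFs were not used as pairs, since 5 of 18 correlations of same-number deviations were over 0.1 (from -0.388 to 0.63) and 4 of 12 arrays matched their own number best. All 5 lay among the groups with factors, where replicate 2 gave 0.568, 0.373 and 0.576 and replicate 1 ran from -0.388 to 0.134. A batch shared by some of these arrays is thus not excluded. With the numbers as a block the counts were 15863 for KOSM against vector, 3 for KOSMBAN against KOSM and 523 for deficient against wild-type MEFs. Signal over background limits dim genes such as Npm2, at or below the 32nd percentile in every group.

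Array weights ran from 0.0786 to 4.38 among MEFs and gave 797 genes for KOSMBAN against KOSM MEFs and 1922 for deficient against wild-type MEFs. In the 4 fits with ES cells their estimation did not converge and put a weight of 129 on R1 with vector MEFs and of 56.9 among pluripotent cells; these gave 13180 genes for ES cells against vector MEFs, 10284 for KOSM and 10593 for KOBAN clones against ES cells, and 1379 for KOBAN against KOSM clones. With them Nanog was 0.004 and the ES-high and MEF-high sets 0 and 0.032 in KOSMBAN MEFs, and Klf4 -0.057 in deficient MEFs. In KOSM clones against ES cells Klf4 was -0.262, Sox2 -0.053, H2bc1 0.029 and Npm2 -0.014, in KOBAN clones Sox2 -0.09 and Npm2 -0.083, and between the clones Npm2 was -0.069. Fitted on the compared groups only, the counts were 214 for deficient MEFs, 6 and 21 for KOSM and KOBAN clones against ES cells, and 850 between the clones, and on all 21 arrays 226, 2653, 4061 and 629. At least 2-fold, 3602, 4755 and 103 genes were called for ES cells, KOSM and deficient MEFs.

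Quantile normalization gave 9783 genes in KOSM against vector MEFs, and 1009 at least 2-fold. There Myc was -0.537, Nanog -0.211, Pfkp -0.148 and the ES-high and MEF-high sets 0.124 and -0.13, and with centred arrays Myc was -0.397, Nanog -0.313, Sox2 -0.222, Hk1 -0.217 and the sets 0.102 and -0.065. ES-high genes turned from below to above the rest with dim genes left out (1.007) and with the sets taken at 2-fold (0.801), where MEF-high genes lost the call (0.728), as they did with an estimated correlation (0.613). Centring left Klf4 at -0.032 in ES cells against vector MEFs. Quantile normalization left H2ac1 at 0.02 and H2bc1 at 0.051 in deficient MEFs, and Sox2 at 0.003 between the clones. With dim genes left out, X-linked genes passed in deficient MEFs (-0.161) and naive-state genes turned to below the rest in KOSMBAN MEFs (0.009). In KOSMBAN MEFs the ES-high set lost its call with centred arrays (-0.014), with the compared groups only, all 21 arrays, the 9 arrays or an estimated correlation (-0.013 each). So did the MEF-high set with the last 4 (0.034 each) and at 2-fold (0.018), and with an estimated correlation in deficient MEFs (-0.215). At an unadjusted p under 0.01, 36 genes overlapped between KOSMBAN and deficient MEFs.

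Leaving out 1 array at a time moved the counts from 2 to 5 for KOSMBAN against KOSM MEFs, 294 to 795 for deficient against wild-type MEFs, 0 to 2970 and 41 to 4475 for KOSM and KOBAN clones against ES cells and 8 to 152 between the clones. Counts within lists moved too, for X-linked genes in KOBAN clones against ES cells from 2 to 178. In ES cells against vector MEFs Klf4 ran from -0.156 to 0.152 and Npm2 from -0.018 to 0.163. In KOSMBAN MEFs Nanog ran from -0.056 to 0.04, X-linked genes from -0.029 to 0.009, the ES-high set from -0.022 to 0.005 and the MEF-high set from 0.022 to 0.046. In deficient MEFs H2ac1 ran from -0.093 to 0.02, H2bc1 from -0.079 to 0.116, Klf4 from -0.05 to 0.048 and X-linked genes from -0.107 to 0. Ranges in KOSM clones against ES cells were -0.065 to 0.243 for Klf4, -0.315 to 0.186 for Npm1, -0.019 to 0.161 for H2ac1 and -0.004 to 0.58 for Sox2, and in KOBAN clones -0.032 to 0.552 for Sox2, -1.81 to 0.003 for Myc and -0.001 to 0.208 for Npm2. Between the clones they were -0.148 to 0.079 for Pou5f1, -0.07 to 0.139 for Npm2, -0.089 to 0.018 for Sox2 and -0.24 to 0.083 for Nanog.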

Other observations

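The tests of carry-over and of a single clone in this part were chosen after the result was seen. A set of mesothelial surface genes moved in a way that the comparisons above give only for Lrrn4 and Upk3b in KOSMBAN MEFs. Lrrn4, Upk3b, Upk1b and Gpm6a, which mark the lining of body cavities, were higher in KOSM MEFs than in vector MEFs on every array, by more than the median shift of 0.617. From that level they were lower in both other groups with factors: Lrrn4 by -0.88 (SE 0.13) in KOSMBAN MEFs and -1.42 (SE 0.13) in deficient MEFs, Upk1b by -0.84 and -1.16, Upk3b by -0.77 and -1.03, and Gpm6a by -0.80 and -1.45. In deficient cells all 4 were called (limma adjusted p = 9.02e-05 for Lrrn4 and 0.0016 for Upk3b), and in KOSMBAN cells none was (adjusted p = 0.102 for Lrrn4 and 0.5 for Upk3b). These genes were chosen after their values were seen, and both differences share the KOSM arrays. At an unadjusted p under 0.01, 16 genes were lower in both comparisons where 0.641 would be by independent calls, and the shared arrays alone raise that number; 14 were higher in KOSMBAN and lower in deficient cells (1.31 by independent calls). Without 1 MEF array at a time these numbers ran from 8 to 40 and from 3 to 19.

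The X-inactivation transcript Xist had a mean intensity of 67.8 ± 23.7 (SD, n = 3) in KOBAN clones, 21.7 ± 1.27 in KOSM clones and 35.5 ± 14 in ES cells. The Y-linked gene Uty leaned upward in the KOBAN clones at the same time (1.05 against KOSM clones, SE 0.32, limma adjusted p = 0.333). Kdm5d, also Y-linked, did not set the clones apart, with 1.31 in KOSM and 1.28 in KOBAN clones against ES cells. The ES lines differed among themselves more than the clones did. The SD over genes of the difference between an ES line and the mean of the iPS clones was 0.393 for TT2, 0.455 for R1 and 0.906 for E14, and E14 had 2393 genes at least 2-fold under the other lines. The deviations of E14 correlated across genes with those of replicate 3 of the deficient MEFs (r = 0.654), which had 1455 such genes. Genes of long genomic span were low relative to short ones by -0.392 in E14; the -0.132 of that replicate was near the -0.106 of replicate 2 of the vector MEFs and so is not particular to it.

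The fibroblast genes that were higher in KOBAN than in KOSM clones may come from fibroblasts left in the cultures. Fibroblasts like the vector MEFs were argued against, since the median share implied by 19 fibroblast genes was 22.6%, 5.83% and 4.87% in clones 3, 6 and 7 and that by interferon genes at most 0.0921%, a ratio of 0.00408. A single aberrant clone was argued against too, as the list's mean shift was 1.15 without clone 3 and 1.54 with it. Fibroblasts without an interferon response stay open, because of 100 abundant fibroblast genes, with median shares of 9.97%, 3.84% and 3.18%, 22% in clone 3, 26% in clone 6 and 23% in clone 7 implied less than 0.333 of their clone's median, too many for 1 common share and too few to rule it out. Lyz2, at 7.82 or more in each KOBAN clone and at most 6.4 in any MEF array, is not explained by these MEFs. Fabp7 was at 9.37 to 10.66 in KOBAN clones and at most 5.6 in any vector MEF array, so vector MEFs do not explain it either. In MEFs with factors it was at most 9.71, in whole cultures and in the other set of values. A difference between the factor sets remains untested.

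A lower share of mesothelial cells in KOSMBAN than in KOSM cultures may explain the first pattern there, and it stays open. A further 12 mesothelial genes were listed as not seen before. They are not fully separate from the pattern, since Aldh1a2 was among the genes lower in both comparisons, and Krt8 and Krt18 were on the epithelial list. Their mean was -0.088, with 7 of 12 lower. Camera in limma gave an adjusted p = 0.000776 in the direction of a fall, equal to the unadjusted p since 1 list was tested. With an estimated correlation it was 0.075, which did not pass. Aldh1a2 was not called (-0.42, SE 0.11), and neither were Msln (-0.12, SE 0.15) or the brightest of the 12, Efemp1 (0.01, SE 0.1). In deficient MEFs the same 12 were not lower (mean 0.068, 4 of 12 lower, camera adjusted p = 0.926), with Krt8 called higher (0.78, SE 0.12) and Aldh1a2 called lower (-0.83, SE 0.11), which goes against a lower share of such cells there without excluding it.

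The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called the most genes in each comparison, 1 of 10 in all cases. Every other split mixes arrays of both groups, so a group difference of any source widens its spread and keeps its calls few. The low counts of the other splits are thus no evidence for the real ones. The counts were 6510 for ES cells against vector MEFs, 16005 for KOSM against vector MEFs, 3 for KOSMBAN against KOSM MEFs, 586 for deficient against wild-type MEFs, 107 for KOSM clones and 206 for KOBAN clones against ES cells, with 0 as the highest of the other splits. For KOBAN against KOSM clones it was 50, and 1 in the highest other split.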
